A study of Mus musculus with 3 samples.

How the data were processed

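CDX2 ChIP-seq was carried out in mouse trophoblast stem cells of a wild-type strain, with 2 immunoprecipitated samples and 1 input sample. By its strain name, the line carries an inversion on the X chromosome. Per the labels' protocols, cells were fixed with paraformaldehyde, chromatin was sheared by sonication, CDX2 was precipitated with a commercial antibody, and libraries were sequenced paired-end. Per the submitters' processing notes, the tools were cutadapt 1.9.1, BWA 0.6.2, Picard, MACS2 2.1.1.20160309, HOMER 4.8 and bedtools, and the genome build was mm10. The notes used here give no role, order or setting for them. The deposited files are 1 peak list per immunoprecipitation, so replicates were called separately. No file of the input sample was used here, and whether that sample served as the control of the peak calls was not given in the sources used here. If it did, the backgrounds of both lists rest on the same sample and are not independent.

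In each deposited list the authors give, per peak, the start, end and summit, the fold enrichment as a linear ratio, and the p-value and q-value as −log10. The deposited score is 10 times the −log10 q without its decimals and was not used. These values are the authors' own per peak and served only to rank, filter and describe peaks within a list. The lowest −log10 q was 1.32 in replicate 1 and 1.30 in replicate 2. The lists hold no read totals. The fold ratio and p-value of each peak were solved together for the fragment pileup at the summit, a whole number, and for the local background behind the test, taking fold as (pileup + 1) / (background + 1) and p as the upper Poisson tail. With a tolerance of 0.005 in −log10 p, this gave a solution for 31885 of 31885 peaks in replicate 1 and 26209 of 26210 in replicate 2. On 2000 simulated peaks it returned the exact pileup in 100.0%, and it found a solution for 2.10% of peaks with shuffled p-values. The lowest background was 3.81 fragments in replicate 1 and 2.94 in replicate 2, a ratio of 1.30.

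Analyses used the 31885 and 26210 peaks on assembled chromosomes and left out 10 peaks per list on unplaced scaffolds. Coordinates are 1-based on mm10. Overlapping peaks (at least 1 bp) were merged, and a shared region is a merged region with a peak of both replicates. Its rank is the worse of its 2 within-list ranks by q-value, and its position is the midpoint of the best summits. Random expectations came from 100 placements of single peaks within the annotated span of their own chromosome, the Y chromosome included. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

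Gene positions came from a RefSeq gene table on the patched release of the same assembly, which has gene ends but no strand, exons or transcription start sites. Windows planned around the transcription start site were therefore drawn as 10 kb on each side of both gene ends, and classes of exon and intron were not computed. No genome sequence was used, so the planned motif comparison was not run. For 18 gene lists, the share of members with a shared region in the window was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over the lists, at a threshold of 0.05. All 413 listed genes matched the 21887 protein-coding genes. Some genes stand in more than 1 list, such as Tfap2c, Fgfr2, Spry4, Vgll1, Ets2, Cdkn1a and Cdkn1c. In simulation on 21887 genes, lists of at least 20 genes with 70% of members bound were called in 100.0% of draws and random lists in 1.15%. Bound genes were drawn independently, with the same planted share in each draw. Lower shares and neighbouring genes that share a region were therefore not simulated. In simulated overlaps of 31885 peaks, planted shares of 30% and 70% were returned as 30.4% and 70.0%.

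Groups, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named were Cdx2 and Tfap2c, up to 4 members per list with the best ranked shared region, up to 3 members of the trophoblast lists with no peak (alphabetically), the 10 best ranked regions with the nearest protein-coding gene, and the 10 genes with most shared regions within 50 kb. Alternatives were a 50% reciprocal overlap, summits within 100 bp, −log10 q of at least 5 or 10, lists of equal length, ranking by fold, windows of 5 kb and 50 kb, the nearest gene end only (at any distance), either replicate alone, and 10000 random lists matched on gene length and neighbour distance, each cut into 5 equal classes. For matched lists and for lists moved along the gene order, the odds ratio sets the observed number of members against the mean of the random lists, with 0.5 added to each count. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.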

Results

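Mouse trophoblast stem cells, the self-renewing cells of the early placental lineage, were examined by chromatin immunoprecipitation followed by sequencing (ChIP-seq) for CDX2, a caudal-type homeobox transcription factor of trophectoderm. The series held 3 samples: 2 CDX2 immunoprecipitations, described in the labels as independent, and 1 input sample of chromatin without immunoprecipitation. Each immunoprecipitation came with its own peak list on mouse build mm10, with 31895 peaks for replicate 1 and 26220 for replicate 2. The input sample entered no comparison of its own. Fold enrichment and q-values per peak are those of the authors' peak caller and were used only to describe, rank or filter peaks within a list. Total read numbers per library were not given in the sources used here, so depth was gauged from the fragments and background behind each peak. The median summit was covered by 29 fragments in replicate 1 and by 28 in replicate 2, over lists of different length. Over the same 22312 regions with a peak of both, replicate 1 had a median of 1.18 times the fragments of replicate 2, and its lowest background was 1.2955 times as high.

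The labels place CDX2 and TFAP2C together in the title of the study, and the first question was whether the loci of these regulators held CDX2 peaks in both immunoprecipitations. Regions holding a peak of both replicates are called shared regions. Cdx2 itself, on chromosome 5 from 147300900 to 147307249, had 6 shared regions within 10 kb of its ends and 10 within 50 kb. The best ranked of the 6 lay 2859 bp outside the gene, with 11.4-fold enrichment in replicate 1 and 12.7-fold in replicate 2. Tfap2c, which encodes the AP-2 gamma transcription factor of trophoblast, lies on chromosome 2 from 172545678 to 172558622 and had 3 shared regions within 10 kb. The best ranked spanned 172543978 to 172545118, outside the gene with its summit 901 bp from the nearer end, and was enriched 52.5-fold in replicate 1 and 53.7-fold in replicate 2. It stood at position 525 of the replicate 1 list and 562 of the replicate 2 list. Elf5 and Eomes, further trophoblast regulators, were added to the map after their values had been seen. Elf5 had 1 shared region within 10 kb of its ends and 7 within 50 kb, the highest at 51.7-fold and 49.3-fold, and Eomes had 5 and 9, the highest at 38.0-fold and 33.5-fold.

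**Figure D1:**
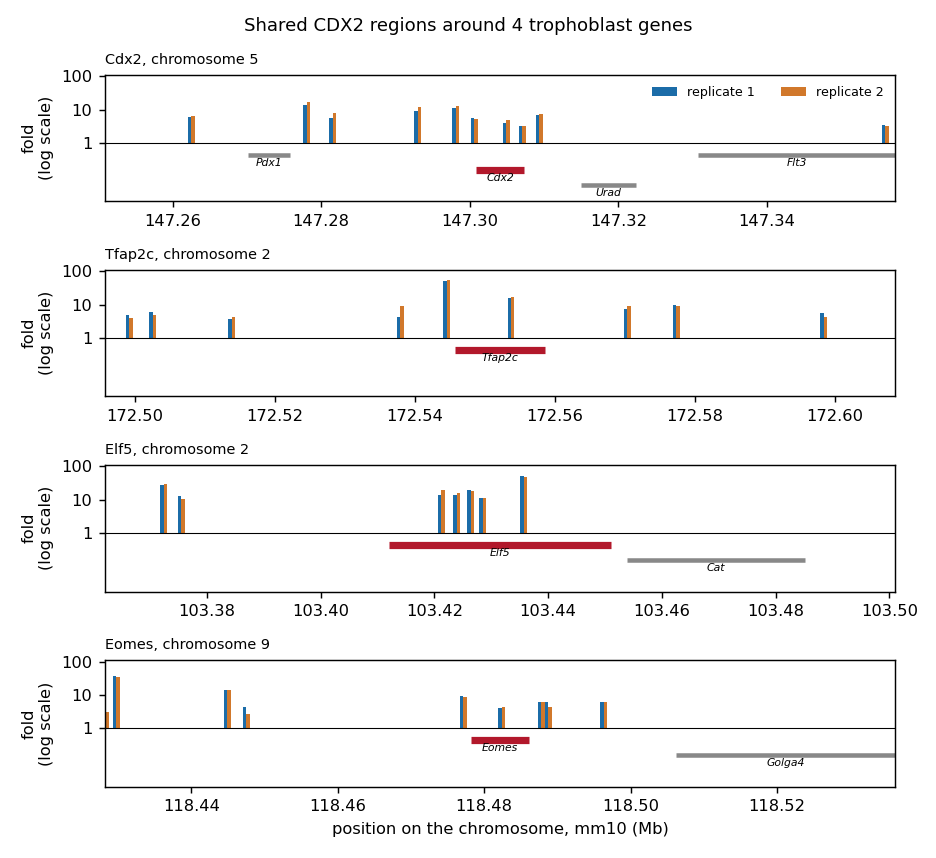
Shared CDX2 regions around Cdx2, Tfap2c, Elf5 and Eomes, with 50 kb on each side. Bars give the fold enrichment of the best peak of each replicate in a shared region (log scale) against position on mm10 in Mb, and horizontal bars below mark protein-coding genes, with the named gene in red. The tallest pair at Tfap2c stands at 52.5-fold and 53.7-fold beside the end of the gene, and the highest at Cdx2 reach 13.9-fold and 17.4-fold.

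Genes that keep trophoblast stem cells self-renewing were the list most often accompanied by shared regions. Of 26 such regulators, 21 (80.8%, 95% exact interval 60.6 to 93.4) had a shared region within 10 kb of a gene end, against 6106 of all 21887 protein-coding genes (27.9%). The odds ratio was 10.9 (two-sided Fisher's exact test, adjusted p = 2.81e-07 over 18 lists). After Tfap2c, the best ranked were Lin28a, an RNA-binding protein of stem cells (45.9-fold and 51.7-fold in replicates 1 and 2), Spry4, a feedback inhibitor of receptor tyrosine kinase signalling (23.6-fold and 25.2-fold), and Fgfr2, the receptor through which FGF4 maintains these cells (21.1-fold and 28.9-fold). Esrrb and Duxbl1 had no peak of either replicate in that window, although 11 shared regions lay within 50 kb of an end of Esrrb. Satb2, Kdm1a and Tcf7l1 each had a peak of replicate 1 alone, and are named here after their values were seen.

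FGF and ERK signalling genes, which act downstream of the growth factor these cells depend on, were also accompanied by shared regions more often than other genes. A region lay near 18 of 26 members (69.2%, odds ratio 5.83, Fisher's exact test, adjusted p = 6.31e-05). Etv5, an ETS factor induced by FGF signalling, held a region enriched 60.6-fold and 62.4-fold inside the gene. Spred2, an inhibitor of the RAS to ERK cascade, had 5 shared regions, the best at 21.3-fold and 22.8-fold, and Spry4 and Fgfr2 were the next ranked. The epithelial junction and keratin genes had a shared region at 19 of 26 members (73.1%, odds ratio 7.03, Fisher's exact test, adjusted p = 1.33e-05). Their best ranked members were the claudins Cldn7 (75.8-fold and 95-fold) and Cldn3 (39.4-fold and 41.8-fold), the epithelial transcription factor gene Grhl3 (22.5-fold and 23.5-fold) and Cdh1, which encodes E-cadherin (18.3-fold and 17.5-fold).

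Hox genes, the clustered homeobox genes of axial patterning, had a shared region at 29 of 39 members (74.4%, odds ratio 7.53, Fisher's exact test, adjusted p = 4.01e-08). The 39 genes shared 36 distinct regions, and members were covered in each cluster: 10 of 11 in Hoxa, 7 of 10 in Hoxb, 7 of 9 in Hoxc and 5 of 9 in Hoxd. A single region on chromosome 15, from 103014160 to 103015259, lay inside Hoxc5 and within 10 kb of Hoxc4 and Hoxc6, and was enriched 164-fold in replicate 1 and 216-fold in replicate 2. The region inside Hoxd3 followed at 90.2-fold and 117-fold. When each shared region was given to its nearest gene end at any distance, the Hox list did not pass (odds ratio 1.89, Fisher's exact test, adjusted p = 0.0887). It passed when only nearest ends within 10 kb counted, a setting added after the data were seen (odds ratio 4.18, Fisher's exact test, adjusted p = 5.81e-05).

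Of the lists of differentiated trophoblast, only the spongiotrophoblast and ectoplacental cone genes passed the test, with 14 of 26 members (53.8%, odds ratio 3.02, Fisher's exact test, adjusted p = 0.0247). Cited2, a transcriptional co-regulator needed for placental growth, had a region at 38.3-fold and 41.4-fold, followed by Pcdh12 (17.5-fold and 12.8-fold), Ets2 (16.8-fold and 15.2-fold) and the growth factor gene Igf2 (13.1-fold and 14.0-fold). Arnt, Cdkn1c and Cited1 had no peak within 10 kb, and 2 shared regions each within 50 kb. By Fisher's exact test, this list lost its call at −log10 q of at least 10 (odds ratio 2.13, adjusted p = 0.203), with windows of 5 kb (2.28, adjusted p = 0.164), with replicate 2 alone (2.55, adjusted p = 0.0679) and, with fewer genes, without chromosomes 1, 8, 11 and X (2.93, adjusted p = 0.0512). The trophoblast giant cell genes reached 12 of 24 members (50%, odds ratio 2.59, adjusted p = 0.0653 by Fisher's exact test) and did not pass. The best ranked of them was Hand1, a basic helix-loop-helix factor required for giant cell formation, whose region 4945 bp from the gene was enriched 61.0-fold and 91.0-fold. Regions also lay at Prl6a1, a prolactin family member (29.5-fold and 31.5-fold), Serpinb9g (19.1-fold and 17.0-fold) and Lifr (14.8-fold and 15.5-fold), while Bhlhe40, Cdkn1c and Ctsq had no peak within 10 kb, and 4, 2 and 0 shared regions within 50 kb. Against random lists matched on gene length and neighbour distance, the giant cell list did pass (permutation test, adjusted p = 0.0252). It also passed with the nearest gene end only, at any distance (odds ratio 4.87, Fisher's exact test, adjusted p = 0.00190). The syncytiotrophoblast genes had 11 of 22 members with a region (50%, odds ratio 2.59, adjusted p = 0.0772 by Fisher's exact test) and did not pass. Cebpa had a region at 48.0-fold and 54.1-fold, the TEAD cofactor gene Vgll1 at 60.5-fold and 71.5-fold, the lactate transporter gene Slc16a1 at 27.9-fold and 26.6-fold and the transferrin receptor gene Tfrc at 17.6-fold and 28.2-fold, and Cebpb, Dlx3 and Fzd5 had no peak within 10 kb, and 1, 2 and 1 shared regions within 50 kb.

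In the TFAP2 family, 2 of 5 genes had a shared region (odds ratio 1.72, adjusted p = 0.748 by Fisher's exact test): Tfap2c and Tfap2a, the latter at 8.73-fold and 9.64-fold. Tfap2b had a peak of replicate 1 alone, and Tfap2d and Tfap2e had none within 10 kb and no shared region within 50 kb. Among mitotic cell cycle and endocycle genes, 11 of 30 had a shared region (36.7%, odds ratio 1.5, adjusted p = 0.438 by Fisher's exact test). With peaks of replicate 1 alone, 20 of 30 did and the list passed (odds ratio 3.14, Fisher's exact test, adjusted p = 0.00861). The housekeeping comparison list also passed in that setting, with 16 of 24 members, so this call was not particular to cell cycle genes. The best ranked cell cycle genes were the replication licensing genes Cdc6 (14.6-fold and 13.4-fold) and Cdt1 (8.22-fold and 7.85-fold), the MYB family gene Mybl2 (12.3-fold and 12.7-fold) and the cyclin-dependent kinase inhibitor gene Cdkn1a (10.2-fold and 8.62-fold).

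The remaining signalling and lineage lists did not pass either. Under some alternatives given below, the TGF-beta, Hippo and primitive endoderm lists did pass. Of the TGF-beta, Nodal and BMP genes, 12 of 25 had a region (adjusted p = 0.0845 by Fisher's exact test), led by the activin receptor gene Acvr1b at 145-fold and 163-fold, with Skil (23.4-fold and 21.2-fold), Pcsk6 (16.6-fold and 14.7-fold) and Id1 (11.7-fold and 9.02-fold) after it. The Hippo pathway had 10 of 23 (adjusted p = 0.190 by Fisher's exact test), with Vgll1, Nf2 (26.0-fold and 44.9-fold), Tead3 (11.6-fold and 12.1-fold) and Tead4 (11.1-fold and 13.2-fold) ranked first. Pluripotency genes had 9 of 20 (adjusted p = 0.213 by Fisher's exact test), among them Dppa4 (24.5-fold and 26.9-fold), Utf1 (19.3-fold and 14.3-fold), Pou5f1 (15.2-fold and 20.3-fold) and Dppa2 (10.0-fold and 7.92-fold). Primitive endoderm genes had 10 of 20 (adjusted p = 0.0845 by Fisher's exact test), with Lamb1 at 41.3-fold and 42.2-fold, Fgfr2, and the adjoining Col4a1 and Col4a2 at 9.41-fold and 9.25-fold from a single region.

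Genes of the intestine, another tissue where CDX2 acts, were not accompanied by shared regions more often than other genes in these cells. A region lay near 6 of 27 members (22.2%, odds ratio 0.738, adjusted p = 0.752 by Fisher's exact test), including the brush border gene Vil1 (37.4-fold and 42.9-fold), the paralogue Cdx1 (20.9-fold and 20.1-fold), Fabp1 (10.4-fold and 13.3-fold) and Guca2a (4.36-fold and 4.12-fold). The labels mention medium conditioned by embryonic fibroblasts, and 3 of 20 fibroblast genes had a region (15%, adjusted p = 0.438 by Fisher's exact test): Loxl1 (23.3-fold and 39.6-fold), Pdgfrb, whose region is the one also counted for Cdx1, and Lum (10.2-fold and 8.12-fold). The comparison lists gave 6 of 25 neuronal genes (adjusted p = 0.873), 7 of 25 hepatocyte genes (adjusted p = 1.00) and 9 of 24 housekeeping genes (adjusted p = 0.464), each by Fisher's exact test. Their best ranked members were Syt1, Syp, Slc17a7 and Sst, then Hpd, Trf, Tat and Pck1, and then Tbp, Ubc, Gapdh and Rpl13a, with fold enrichments in replicate 1 from 4.41 at Pck1 to 24.2 at Tbp. In all, 5 of the 18 lists passed, against 8 with replicate 1 alone, 4 with replicate 2 alone and 9 when each region counted only for its nearest gene end within 10 kb. These tests describe 2 libraries, since genes are not replicates, and neighbouring genes can share a region.

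**Figure D2:**
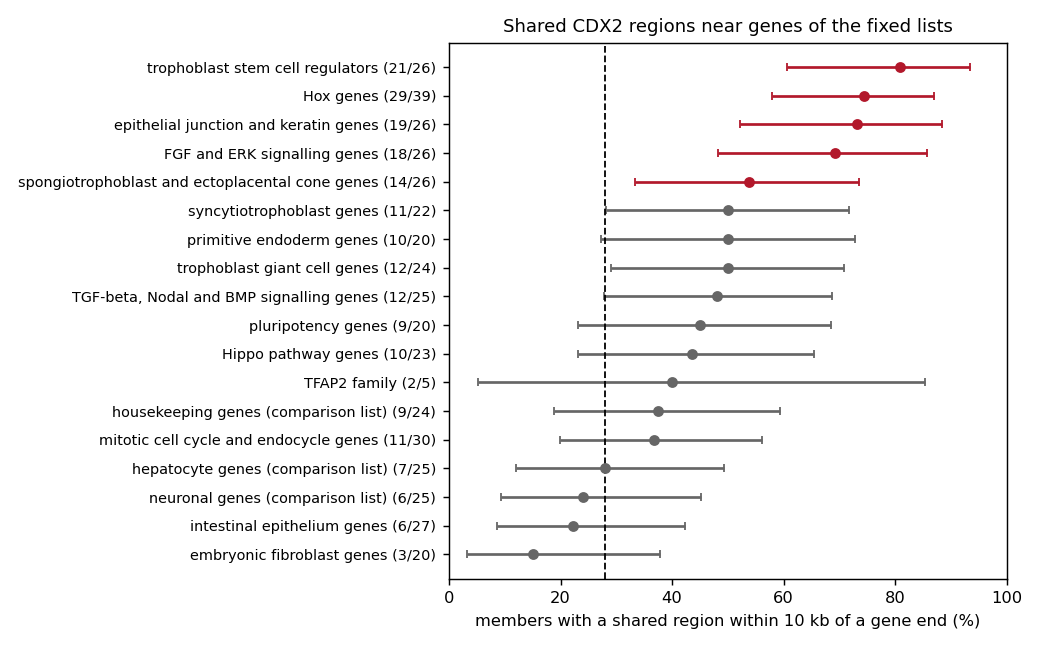
Percentage of the members of each fixed gene list with a shared CDX2 region within 10 kb of either gene end, with exact 95% intervals and the number of members in brackets. The dashed line marks the 27.9% of all protein-coding genes, and red marks the 5 lists that passed the two-sided Fisher's exact test after adjustment, from 53.8% to 80.8%.

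The strongest shared regions of the genome stood mostly outside protein-coding genes. The best ranked in both replicates lay on chromosome 19 from 4946318 to 4949110, 3880 bp from Peli3, which encodes an E3 ubiquitin ligase, and was enriched 321-fold in replicate 1 and 353-fold in replicate 2. The next, on chromosome 16 from 8885348 to 8886343, lay 26853 bp from 1810013L24Rik inside a long non-coding RNA gene, at 282-fold and 292-fold. Those ranked 3 to 5 lay 66301 bp from Cwc22 on chromosome 2, 53084 bp from LOC115488029 on chromosome 12 and 47839 bp from Gm15319 on chromosome 8. The region ranked 6 spanned 7014838 to 7015801 on chromosome 15, 75339 bp from the receptor gene Lifr, with 289-fold and 358-fold enrichment. Ddc, which encodes aromatic L-amino acid decarboxylase, contained the region ranked 7 (chromosome 11, 11821900 to 11823449, 156-fold and 185-fold), and the transcription factor gene Sox13 the one ranked 10 (chromosome 1, 133397423 to 133398276, 147-fold and 171-fold). Those ranked 8 and 9 lay 12450 bp from Pck1, the gene of a gluconeogenic enzyme, and 22183 bp from Sppl2a. The regions ranked 3 to 5 had backgrounds of 12.2, 9.44 and 18.1 fragments in replicate 1 and 10.1, 7.58 and 14.2 in replicate 2. The list medians were 4.24 and 3.47, and among the best ranked 10 only the region near Lifr lay below both. The region near Gm15319 lay inside a transcribed pseudogene. Whether reads at these sites map uniquely was not tested.

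Some genes were surrounded by many shared regions. Myh9, which encodes non-muscle myosin heavy chain, had 19 within 50 kb of its ends, against a median of 1 over all protein-coding genes and a 99th percentile of 9. Reep3 and Sipa1l2 had 18 each, Zcchc2 had 17, Zfp608 had 16, and Cox10, Ddc, Errfi1, Klhl22 and Piezo1 had 15 each. Among the best ranked region of each gene, the highest folds after the one in Ddc were at Zfp608 (79.6-fold and 105-fold), Klhl22 (74.5-fold and 68.6-fold) and Zcchc2 (70.8-fold and 65.2-fold). No gene within 50 kb was excluded for lying close to another, so a region can count for several genes. Zcchc2 on chromosome 1, Sipa1l2 and Piezo1 on chromosome 8 beyond 100 Mb, and Cox10 and Ddc on chromosome 11 below 70 Mb lay in segments of raised background. Myh9, Reep3, Zfp608, Errfi1 and Klhl22 lay outside such segments. Whether the raised background added to these counts was not tested.

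How far the immunoprecipitations found the same sites was asked next. On the assembled chromosomes, 22408 of 31885 replicate 1 peaks (70.3%, 95% exact interval 69.8 to 70.8) were overlapped by at least 1 bp by a replicate 2 peak, and 22616 of 26210 replicate 2 peaks (86.3%, 85.9 to 86.7) by a replicate 1 peak. Placing the other list at random within its chromosomes gave 0.913% (SD 0.0534) and 1.12% (SD 0.0658) over 100 placements. Merging all peaks gave 35383 regions, of which 22312 (63.1%) held a peak of both replicates, 9477 of replicate 1 alone and 3594 of replicate 2 alone. In shared regions, the summits of the best peaks lay a median of 26 bp apart, and 74.4% lay within 50 bp.

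Strong peaks were found in both lists and weak ones often in one. In the strongest 10% of each list by q-value, all 3189 peaks of replicate 1 and 2620 of 2621 peaks of replicate 2 were overlapped by the other list. In the weakest 10% these shares were 21.5% (20.1 to 23.0) for replicate 1 and 53.8% (51.8 to 55.7) for replicate 2. The replicate 1 list is longer, and its share of overlapped peaks rose to 80% when both lists were reduced to their 26210 best peaks.

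**Figure D3:**
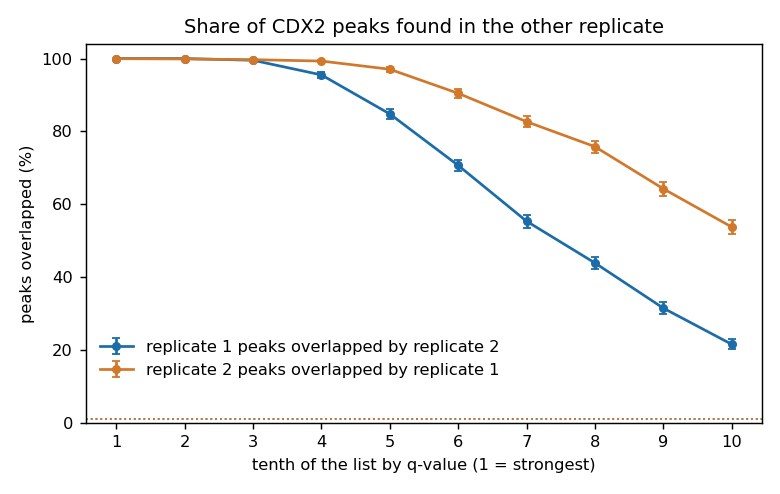
Percentage of CDX2 peaks of each replicate overlapped by the other replicate, for each successive 10% of the list ranked by q-value, with exact 95% intervals. Dotted lines mark the means of random placement, 0.913% and 1.12%, and the curves fall from 100% to 21.5% in replicate 1 and to 53.8% in replicate 2.

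Relative to genes, shared regions were closer to gene ends than random positions were. Of the 22312 shared regions, 29.9% lay within 10 kb of an end of a protein-coding gene (29.3 to 30.5), against 21.3% of random positions, and 6.13% lay within 1 kb (5.82 to 6.45), against 3.08%. The median distance to the nearest gene end was 25007 bp, against 49221 bp at random. Inside protein-coding genes lay 42.2% (41.5 to 42.8), against 40.3% at random, with no placement above 41.1%. Within 1 kb of a gene end lay 8.77% of replicate 1 summits (8.46 to 9.09) and 6.50% of replicate 2 summits (6.21 to 6.81), falling to 5.20% and 4.58% at −log10 q of at least 10. Which end holds the start of transcription, and whether a region lies in an exon, an intron or a UTR, was not resolved with the annotation used here.

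Peak density differed between chromosomes in the same way in both replicates. Chromosome 11 had 17.8 peaks per Mb in replicate 1 and 14.2 in replicate 2, or 1.51 and 1.46 times the number expected from its length. Chromosome 1 had 16.2 and 13.2 peaks per Mb, 1.37 and 1.36 times the expected number, and the X chromosome 4.18 and 3.61, 0.355 and 0.372 times. The autosomes other than 1, 8 and 11 lay between 0.844 and 1.26 times in replicate 1 and between 0.830 and 1.3 times in replicate 2. Chromosome 8 as a whole lay at 1.06 and 1.07 times, but its peaks were denser beyond 100 Mb, as given under the other observations. Replicate 1 had 0 peaks on the Y chromosome and replicate 2 had 1. When the expectation was taken from the number of protein-coding genes, chromosome 11 lay at 0.925 and 0.897 times and chromosome 1 at 1.80 and 1.79 times. The background recovered from the peak statistics was also raised on chromosome 1 and on chromosome 11 up to 70 Mb, with median ratios to the autosomes other than 1, 8 and 11 of 1.36 and 1.42 in replicate 1 and of 1.38 and 1.47 in replicate 2. These backgrounds may come from 1 common input sample, so the replicates need not be independent here.

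**Figure D4:**
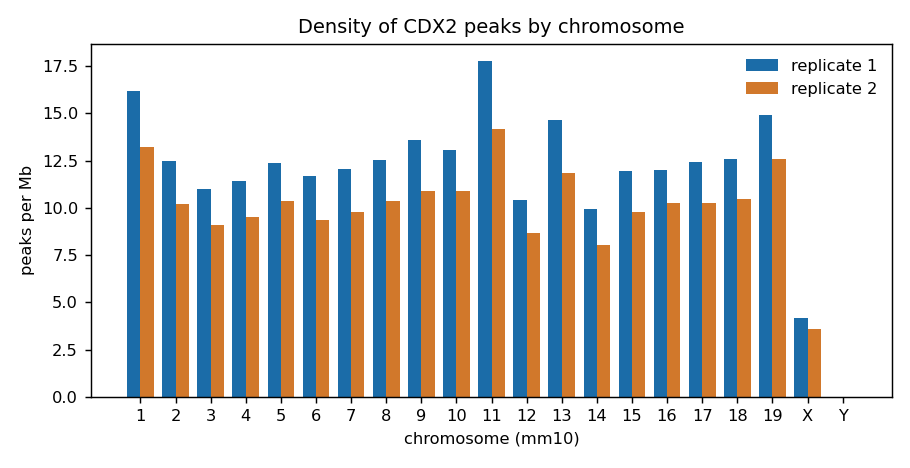
CDX2 peaks per Mb on each mouse chromosome (mm10) in replicates 1 and 2, each bar being 1 list. Chromosome 11 reaches 17.8 and 14.2 peaks per Mb, chromosome 1 reaches 16.2 and 13.2, and the X chromosome 4.18 and 3.61.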

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

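The tests of gene density, the thinning of chromosome 11, the nearest end within 10 kb, the rotations along the gene order and the window sets at Hox clusters were chosen only after the result was seen. Peaks outside the assembled chromosomes entered no comparison, and these scaffolds held 10 peaks in replicate 1 and 10 in replicate 2. One unplaced scaffold, JH584304, accounted for 4 and 5 of them.

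Chromosome 1 carried more peaks than its length predicts, 1.37 and 1.36 times, and the background recovered from the peak statistics was raised there as well. In bins of 10 Mb, the upper quartile of background on chromosome 1 was a median of 1.36 times that of the autosomes other than 1, 8 and 11 in replicate 1 and 1.38 times in replicate 2. Gene density argues the other way on chromosome 1, which had 2.39 peaks per protein-coding gene as a mean of the replicates, and 2.63 and 2.14 singly, above the highest of those autosomes at 2.16 and 1.79. More copies of chromosome 1 in the cells, raising the power to call peaks, remain possible: thinning its fragments by the background ratio lowered observed over expected to 1.28, above the highest of those autosomes in replicate 1 (1.27) and below it in replicate 2 (1.31). On chromosome 11 the background was raised up to 70 Mb, a median of 1.42 and 1.47 times. Thinning there left observed over expected for the whole chromosome at 1.42, and at 1.45 and 1.40 singly, above the highest of those autosomes (1.27 and 1.3). Peaks beyond 70 Mb were not thinned, so this value alone cannot decide. In replicate 1, bins of 10 Mb up to 70 Mb held 138 to 287 peaks, and full bins from 70 to 120 Mb held 167 to 222. In replicate 2 they held 99 to 217 and 136 to 179. Peaks were thus about as dense where the background was not raised, which argues against extra copies up to 70 Mb as the whole cause. Peaks per protein-coding gene cannot decide whether gene density accounts for chromosome 11. Its 1.21 lay within the range of those autosomes, but that range was wide. It ran from 0.862 to 2.16 in replicate 1 and from 0.7 to 1.79 in replicate 2. Other gene-dense chromosomes went both ways in observed over expected. Chromosome 7, with 13.97 genes per Mb, had 1.02 and 1.01, and chromosome 19, with 12.1, had 1.26 and 1.3. Gene density stays open for chromosome 11, and no biological explanation was tested.

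The X chromosome carried 0.355 and 0.372 times the expected peaks. A single X copy may lower the power to call peaks, but thinning all autosomal fragments to 50% raised the X only to 0.527, below the lowest autosome at 0.794 and 0.798. Gene density does not account for it alone either, since the X had 0.688 peaks per protein-coding gene, against a lowest autosome at 0.862 in replicate 1 and 0.70 in replicate 2. The joint effect of a single X copy and gene density was not tested and stays open. Mappability, the inactive X and the X inversion given by the strain name were not tested, and no biological explanation was tested.

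Hox genes share regions with their neighbours, which could raise the count of members near a region. With each region given only to its nearest gene end, members with a region fell from 29 to 21 of 39. The odds ratio fell from 7.53 (95% interval 3.67 to 15.5) to 4.18 (2.22 to 7.84) within 10 kb, and to 1.89 (1.01 to 3.56) at any distance, where the call ended because other genes with a region rose to 38.1%. Against sharing as the whole cause stand 0.0183% of rotations of the list along the gene order with as many members, and 0 of 10000 sets of gene-anchored windows of the clusters' lengths with as many as the 36 shared regions, each counted once (0.009999% with the real set included). With any one cluster left out, at most 0.210% of window sets held as many regions, which argues against binding confined to one cluster, although Hoxb alone was not unusual (10.7% of windows), and no biological explanation was tested.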

How the results depend on the processing

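The settings called added here were chosen only after the result was seen: the circular shift, the high-background filter, the expectation from gene number, the nearest end within 10 kb, the extended gene span, the moved lists, and the runs without some chromosomes or without chemosensory receptor genes. Motif alternatives were not run. No paired analysis was possible because the immunoprecipitations and the input share fewer than 2 replicate numbers and form no tested contrast. Stem cell regulators, FGF and ERK genes and epithelial genes kept their calls under all 12 alternatives, with odds ratios of 7.59 to 22.4, 3.69 to 6.83 and 5.59 to 19.5. The cause was not tested for any change below, unless the setting itself sets it (fewer peaks, fewer genes, a wider window). Read totals were not given in the sources used here, so what depth limits was not tested.

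Overlapped peaks of replicates 1 and 2 were 65.1% and 79.2% with a 50% reciprocal overlap, 63.8% and 77.6% with summits within 100 bp, 74.7% and 87.8% at −log10 q of at least 5, 79.3% and 88.9% at 10, and 80.01% and 80.9% with lists of equal length. Ranked by fold, the weakest 10% had 24.7% and 57.7%, and the strongest 10% of replicate 2 had 100%. Expected from gene number (added), observed over expected in replicates 1 and 2 was 1.80 and 1.79 on chromosome 1, 0.925 and 0.897 on chromosome 11, and 0.507 and 0.533 on the X. At −log10 q of at least 10, chromosome 11 had 1.43 and 1.39. Within 5 kb of a gene end lay 22.2% and 19.4% of summits and 19.1% of shared regions, against 12.7% at random. Within 1 kb at −log10 q of at least 10 lay 5.20%, 4.58% and 4.58%.

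For the lists, 8 passed with the nearest gene end only, at any distance. There, odds ratios were 4.87 (giant cell), 3.45 (TGF-beta), 3.05 (Hippo) and 3.79 (primitive endoderm), now past the threshold, 1.89 (Hox), no longer past it, and 0.811 (cell cycle), 1.98 (fibroblast), 1.27 (neuronal) and 0.763 (hepatocyte), on the other side of 1. At −log10 q of at least 10, syncytiotrophoblast (3.99) and TGF-beta (3.19) passed, spongiotrophoblast (2.13) did not, and cell cycle (0.955), hepatocyte (0.910) and housekeeping (0.955) changed side. With 5 kb windows, syncytiotrophoblast passed (2.98), spongiotrophoblast did not (2.28) and housekeeping changed side (0.860). With 50 kb windows, TFAP2 (0.421), intestinal (1.07) and hepatocyte (0.583) changed side. Against matched lists, giant cell passed (3.04). With the nearest end within 10 kb (added), 9 lists passed, with giant cell (3.57), syncytiotrophoblast (2.98), TGF-beta (3.30) and Hippo (2.75) gaining a call. With the extended gene span (added), TGF-beta (2.79) and Hippo (2.90) passed and hepatocyte changed side (0.723). Without chromosomes 1, 8, 11 and X (added), spongiotrophoblast fell below the threshold (2.93) and hepatocyte changed side (0.949), as it did without chemosensory receptor genes (0.929, added).

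With 1 replicate alone, 4 to 8 lists passed. Odds ratios ranged from 2.55 to 2.97 (spongiotrophoblast, lost without replicate 1), 1.46 to 3.14 (cell cycle), 2.39 to 2.95 (Hippo) and 1.85 to 3.14 (housekeeping), these 3 passing without replicate 2, and 0.610 to 0.850 (hepatocyte). In all, 178 list tests kept direction and call, 16 changed side of 1, 17 gained a call and 5 lost one. Of the values without a test, 15 stayed within their interval and 27 moved beyond it, and of the counts of lists passed, 9 stayed within 1.5 times (4 to 7) and 3 did not.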

Other observations

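All tests in this part were chosen only after the result was seen. Outside the fixed lists, olfactory and vomeronasal receptor genes were the families with the smallest p-values, and had few shared regions. Of 1110 olfactory receptor genes, 68 (6.13%) had a shared region within 10 kb, as had 21 of 355 vomeronasal receptor genes (5.92%), against 27.9% of all protein-coding genes (odds ratios 0.159 and 0.160, Fisher's exact test adjusted over 345 families of at least 8 genes sharing a symbol stem, adjusted p = 8.70e-77 and 5.43e-24). Families with more members near a region were the Arhgap genes, GTPase-activating proteins of Rho family switches, with 20 of 34 (58.8%, odds ratio 3.70, Fisher's exact test, adjusted p = 0.0116), and zinc finger genes named Zfp, with 149 of 397 (37.5%, odds ratio 1.57, Fisher's exact test, adjusted p = 0.00237). The Hoxa genes also passed, with 10 of 11 (Fisher's exact test, adjusted p = 0.00237). They are part of the fixed Hox list, so this repeats a count given above. Moved as blocks along the gene order, the Arhgap family had as many members in 0.00457% of rotations, the smallest share they can give. The Arhgef family went the other way without passing, with 3 of 25 members (12.0%, odds ratio 0.352, Fisher's exact test, adjusted p = 0.556).

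Among 765 Reactome pathways of 15 to 300 genes, 56 passed Fisher's exact test after adjustment, 53 of them with more members near shared regions than other genes. The Rho GTPase cycle had 54 of 121 members (44.6%, odds ratio 2.09, adjusted p = 0.0114), among them Rhoa, Cdc42, Tiam1, Trio and Ect2. EGFR downregulation had 16 of 25 (64.0%, odds ratio 4.60, Fisher's exact test, adjusted p = 0.0114), including Egfr, Cbl, Spry1 and Spry2. Sialic acid metabolism had 19 of 31 (61.3%, odds ratio 4.10, Fisher's exact test, adjusted p = 0.0114), including Gne, Cmas and several sialyltransferase genes such as St3gal4 and St6gal1. Histone lysine methylation enzymes had 26 of 47 (55.3%, odds ratio 3.21, Fisher's exact test, adjusted p = 0.0114), including Ezh2, Eed, Setdb1, Suv39h1 and Ehmt2. The aflatoxin detoxification pathway had 0 of 22 (Fisher's exact test, adjusted p = 0.0207). Members were compared with all other protein-coding genes, whether in a pathway or not. These genes include 1501 chemosensory receptor genes, of which 6.06% had a shared region, against 29.5% of all other genes. A comparison among pathway genes only was not run, so how far this choice raised the number of pathways passed stays open. Pathways share genes, so these counts are not independent of each other, nor of the FGF and ERK list.

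Peaks found in replicate 1 alone lay closer to gene ends than its overlapped peaks. Within 1 kb of a gene end lay 15.1% of the 9477 not overlapped (95% exact interval 14.4 to 15.8) and 6.09% of the 22408 overlapped (5.78 to 6.41). The gap was present at −log10 q under 5 (18.4% against 10.8%), from 5 to 10 (12.5% against 8.38%) and at 10 or more (9.67% against 4.95%). In replicate 2, 8.68% of peaks not overlapped (7.78 to 9.65) and 6.15% of those overlapped (5.85 to 6.48) lay there, but by class the former were at 11.5% against 12.0%, 6.53% against 7.82% and 2.27% against 4.63% in the same classes. With replicate 1 alone, the share of all protein-coding genes with a peak within 10 kb was 38.9%, against 27.9% with a shared region, and 15 of the 18 lists had more members. The largest rises in number were from 11 to 20 of 30 cell cycle genes and from 9 to 16 of 24 housekeeping genes, followed by Hippo genes (10 to 15 of 23) and epithelial genes (19 to 24 of 26).

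The recovered background was raised over whole chromosome segments in both lists. Both may rest on the same input sample, so this agreement need not be independent replication. Relative to the autosomes other than 1, 8 and 11, 13 of 20 bins of 10 Mb on chromosome 1 were more than 25% higher in each replicate, and 3 more were at that limit within 0.001 in replicate 1. On chromosome 11 the median ratio was 1.42 and 1.47 up to 70 Mb, and 1.09 and 1.12 beyond. On chromosome 8 it was 1.00 and 0.995 up to 100 Mb, and 1.46 and 1.47 beyond. Peaks were also denser there: bins beyond 100 Mb held 126 to 261 peaks in replicate 1 and 112 to 218 in replicate 2. Bins up to 100 Mb held 41 to 154 and 29 to 129. Whether the raised background added to this density was not tested. The X had median background ratios of 0.833 and 0.865, limited from below because the background has a floor, at which 66.1% and 58.3% of X peaks lay. Of the bins on the other chromosomes, 0 of 204 in replicate 1 and 0 of 198 in replicate 2 were more than 25% higher, with 1 at the limit in replicate 1, and the boundaries at 70 and 100 Mb were set from these values. The highest background, 1552 fragments in replicate 1 and 1263 in replicate 2, was at a peak near 98.7 Mb on chromosome 2, with a fold enrichment of 1.72 and 2.00.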
